A study of Mus musculus with 12 samples.

How the data were processed

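RNA of CD45+ cells (CD45 is the surface marker of leukocytes) from the prostate of TRAMP mice, a transgenic mouse model of prostate adenocarcinoma, was hybridized to Illumina BeadChips. Per the labels, total RNA was taken up in Trizol, and biotinylated cRNA was stained with Streptavidin-Cy3. The 12 arrays fall into 4 groups of 3 mice, each named after the adoptive T cell transfer (ACT) the mice received. The labels do not expand the name Allo/Y, so the group names are used as they stand. No group without a transfer is among the 12 arrays.

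A table of raw values deposited by the authors gives for each of 45281 probes and each array a signal intensity on a linear scale, neither normalized between arrays nor background-subtracted. Beside it stands a detection p-value, which per the file headers belongs to the same array. A normalized table deposited by the authors holds the same probes as linear intensity whose columns share 1 maximum (35863.8) and 1 75th percentile (187.036), the mark of quantile normalization. Each of its 12 columns correlated best with the raw column of its own array. The submitters name GenomeStudio without a version or settings. The scale, units and normalization were read from the values, since the files do not state them. The main results rest on the raw table, and the authors' normalized values served as an alternative.

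Computation used R 4.3.3 and limma 3.58.1. The neqc function corrected the background from negative-control statistics inferred from the detection p-values, added an offset of 16, quantile normalized the arrays and took log2. Probes with a detection p under 0.05 on at least 3 arrays were kept, which left 23054. Of these, 19235 carried 1 gene symbol and 3819 did not and were left out. For each gene the probe with the highest mean over the 12 arrays was used, which gave 11971 genes, 4832 of them with more than 1 kept probe. Where kept probes disagreed in direction for a gene whose change the report prints, it says so.

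One limma model with a mean per group was fitted to all 12 arrays with empirical Bayes variances (residual degrees of freedom 8, prior degrees of freedom 2.47). Every p from it is two-sided, and adjusted p values are Benjamini-Hochberg values over the 11971 genes within a comparison. A gene was called at an adjusted p under 0.05. A moderated F test asked whether a gene differed among the 4 groups. Gene lists of pathways and cell types, 34 in number, were tested with limma's camera at a preset inter-gene correlation of 0.01 when at least 3 of their genes were measured, with adjustment over the lists. This competitive test asks whether a list's genes shifted relative to all other genes. Camera was run again with the correlation estimated per list, and limma's fry tested whether a list's genes moved on balance in 1 direction. Exact tests on single values were not used, since 3 arrays against 3 cannot give an exact p below 0.1.

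Sample groups, tests, gene lists, the rule for named genes and the first set of other settings were fixed before the data were examined. Named genes are, per comparison, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, unnamed gene models left out. To these come up to 4 members of each called list with the smallest p in the list's direction, and 25 genes named in every comparison. Genes named outside this rule are marked as chosen after their values were seen. A gene not above background on any array of a group is given as a fold bound against the background level, in the words at least, and where only some arrays passed the detection threshold their number is given.

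The settings chosen then changed background correction, normalization, the detection filter, the handling of several probes, the arrays in the fit, the variance model, a minimum fold of 1.5, the list test and the genes shared between lists, and left out each array in turn. Added after the data were seen were the epithelium score as a covariate, a shift of the arrays to an equal mean of genes expressed in all leukocytes, and a fit without 2 arrays that lay apart. The pipeline was tested on simulated data with the same numbers of genes and arrays. At a log2 change of 1 it recovered 49 of 100 changed genes in Tumor+Allo/Y against Allo/Y, 60 in Tumor+Allo/Y against Tumor, 52 in Tumor against Allo/Y and 53 over time, and at a log2 change of 2 it recovered 85, 93, 89 and 89. Unchanged genes called numbered 10, 10, 8 and 11. The simulated genes were independent, and each had the same spread in all groups. In the data the median SD within a group was 0.133 in Allo/Y and 0.289 in Tumor, so the recovery in the data may differ. The number of arrays limits the precision.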

Results

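Gene expression was measured in leukocytes infiltrating the prostate of TRAMP mice after adoptive T cell transfer. Prostates were taken 1 week after Allo/Y transfer (samples 1, 2 and 3), Tumor transfer (samples 4, 5 and 6) or combined Tumor+Allo/Y transfer (samples 7, 8 and 9), and 28 days after the combined transfer (samples 10, 11 and 12). The submitters describe the earlier time as that of acute infiltration. Between 18981 and 21718 of the 45281 probes were above background per array (41.9% to 48%), and the median raw signal ran from 53.8 to 68.9. Changes are log2 differences ± SE from the limma fit with n = 3 arrays per group, unless a fold is given. The 4 groups differed in 5479 of 11971 genes (45.8%) by the F test, and in 3357, 3650 and 3534 without Allo/Y samples 1, 2 and 3. Samples of the same group correlated at 0.9858 to 0.9931 in Allo/Y and at 0.9811 to 0.9864 at day 28, over the log2 values. In the Tumor group samples 4 and 5 correlated at 0.9895, while sample 6 correlated with them at 0.8997 and 0.9254 and with Tumor+Allo/Y sample 9 at 0.9755. Tumor+Allo/Y sample 8 correlated with Tumor samples 4 and 5 at 0.9835 and 0.9825, and with samples 7 and 9 of its own group at 0.9599 and 0.9545.

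**Figure D1:**
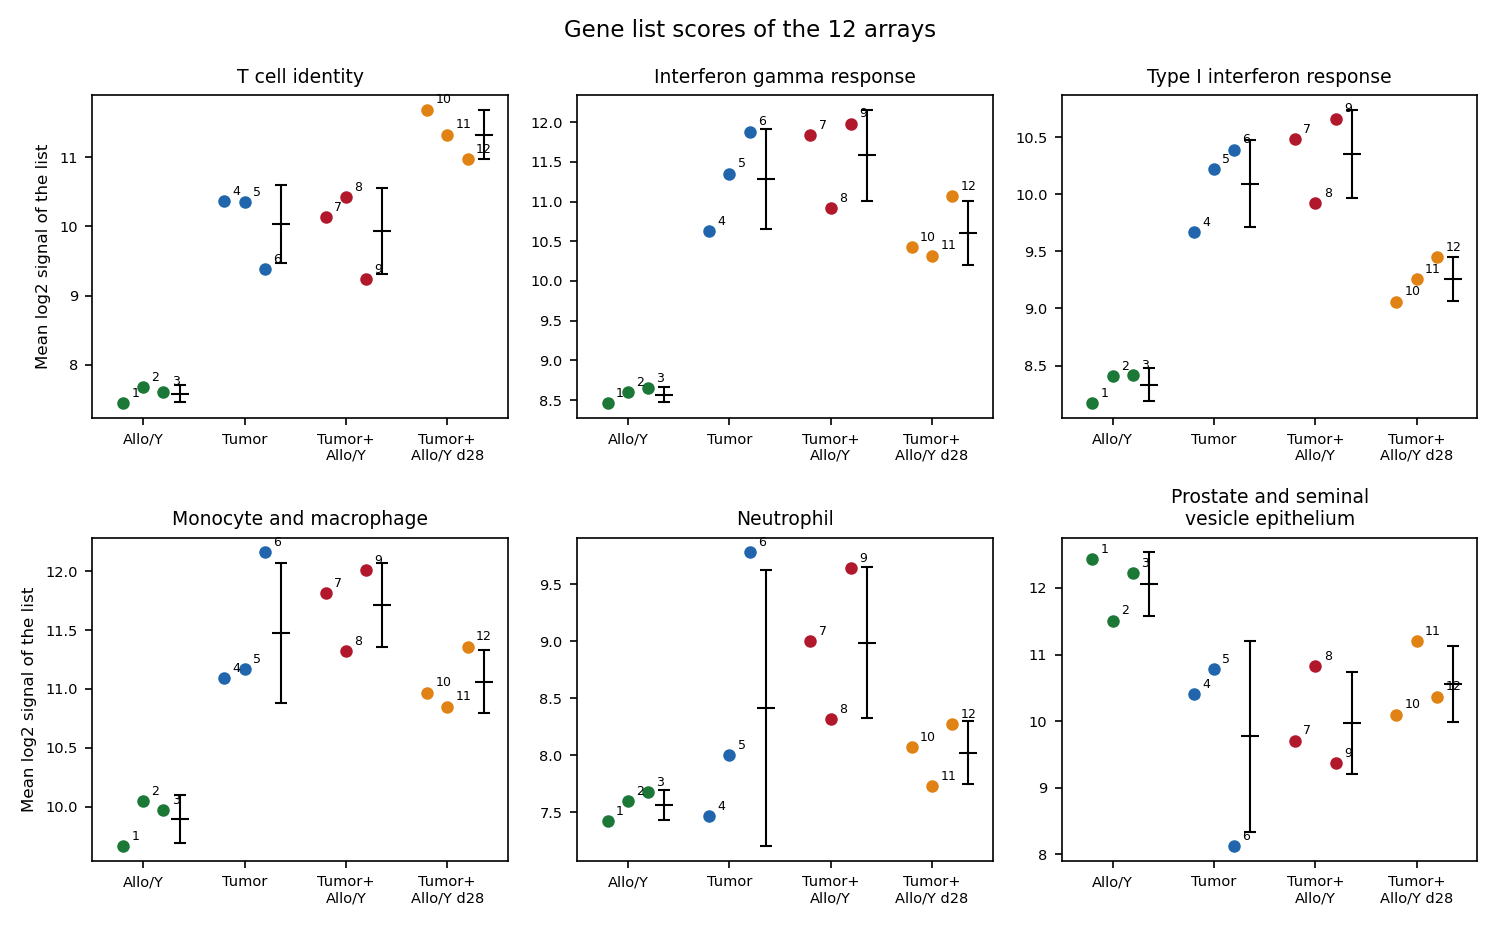
Mean log2 signal of the measured genes of 6 fixed gene lists, 1 point per array with its sample number, and group mean ± SD (n = 3). The T cell, interferon and macrophage scores of all Allo/Y arrays lie below those of the other groups, and within the Tumor and Tumor+Allo/Y groups samples 6 and 8 differ from the others in the neutrophil and epithelium scores.

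What the combined transfer adds to Allo/Y transfer at 1 week was asked by setting Tumor+Allo/Y against Allo/Y. The largest rises included interferon-induced and myeloid genes, a grouping of the ranked genes that was not tested. Gbp2b, which encodes an interferon-inducible GTPase, rose by 6.9 ± 0.65 (119-fold, adjusted p = 6.72e-05), and Cxcl9, a chemokine that draws activated T cells, rose by 4.99 ± 0.38 (adjusted p = 3.23e-05). Chil3 and Chil4, chitinase-like genes of activated macrophages, rose by 6.36 ± 0.68 and 6.37 ± 0.72 (adjusted p = 0.000119 and 0.000154). Ifng, the cytokine interferon gamma, rose by 2.88 ± 0.33 (adjusted p = 0.000176). Svs2, which encodes a seminal vesicle protein, fell by 3.2 ± 0.71 (adjusted p = 0.00469).

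Of 11971 genes, 2467 were higher and 3269 lower in Tumor+Allo/Y, together 47.9%. The other largest rises were those of Serpina3f (5.2 ± 0.49), Calhm6 (5.02 ± 0.7), Slfn1 (4.82 ± 0.4), Acod1 (4.74 ± 0.78), which makes the antimicrobial metabolite itaconate in macrophages, and Batf2 (4.72 ± 0.7). Cfb, complement factor B, was at least 25.6-fold higher, since it was not above background in Allo/Y (adjusted p = 0.000364). The largest fall was that of Cyp4a12a (−4.38 ± 0.3, adjusted p = 2.37e-05), a fatty acid hydroxylase, above background on 2 of 3 Tumor+Allo/Y arrays. Pate14 (−4.27 ± 1.06), Defb42 (−3.76 ± 0.64), Cdo1 (−3.61 ± 0.76) and Pate9 (−3.59 ± 1.08) also fell. Elf5 (−3.8 ± 0.53) and Atp13a4 (−3.55 ± 0.65) were above background on 1 of 3 Tumor+Allo/Y arrays, and Depp1 (−3.58 ± 0.41) and Wfdc6b (−3.48 ± 0.65) on 2 of 3. Spink11 was at least 12.2-fold lower and not above background in Tumor+Allo/Y (adjusted p = 0.000762).

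All 14 measured T cell receptor and identity genes rose, 14 also when adjusted over the list alone (median 2.26, camera adjusted p = 3.54e-08, adjusted p = 0.213 with an estimated correlation). Among them Cd247, the zeta chain of the receptor complex, rose by 2.85 ± 0.24, and Cd3e rose by 2.02 ± 0.4 (adjusted p = 0.00284). All 3 measured CD8 T cell genes rose, 3 adjusted over the list alone (camera adjusted p = 0.0087, adjusted p = 0.181 with an estimated correlation). The coreceptor gene Cd8b1 rose by 2.97 ± 0.32, but another of its 3 probes gave −0.64 and was called lower. Of 14 cytotoxic effector genes 13 rose and 1 did not pass, with 13 risen adjusted over the list alone (camera adjusted p = 1.01e-07, adjusted p = 0.181 with an estimated correlation). Examples are Klrk1, the activating receptor NKG2D, by 3.34 ± 0.3, and the granzyme gene Gzmk by 2.47 ± 0.26. The perforin gene Prf1 gave 0.08 ± 0.27 (adjusted p = 0.82) on the probe used and 2.86, a call, on its other probe. Of 9 inhibitory receptor genes 7 rose and 2 did not pass, with 7 adjusted over the list alone (camera adjusted p = 8.52e-06, adjusted p = 0.181 with an estimated correlation), including Ctla4 (3.58 ± 0.33) and Havcr2 (1.93 ± 0.22). Of 7 regulatory T cell genes 4 rose and 3 did not pass, also 4 adjusted over the list alone (camera adjusted p = 0.00448, adjusted p = 0.181 with an estimated correlation). The lineage factor Foxp3 gave 0.5 ± 0.22 (adjusted p = 0.0783) on the probe used, while its 3 other probes gave 0.57 to 2.63 and were all called higher. Of 7 naive and memory T cell genes 5 rose, 5 adjusted over the list alone (camera adjusted p = 0.00574, adjusted p = 0.209 with an estimated correlation), and of 10 NK cell genes 9 rose, 9 adjusted over the list alone (camera adjusted p = 4.64e-06, adjusted p = 0.181 with an estimated correlation).

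All 25 type I interferon response genes rose, 25 adjusted over the list alone (median 2.12, camera adjusted p = 2.98e-13, adjusted p = 0.181 with an estimated correlation), such as Isg15, a ubiquitin-like antiviral protein, by 2.89 ± 0.22. Of 22 interferon gamma response genes 21 rose and 1 did not pass, 21 adjusted over the list alone (median 2.85, camera adjusted p = 2.98e-13, adjusted p = 0.181 with an estimated correlation). All 15 genes of MHC class II presentation rose, 15 adjusted over the list alone (camera adjusted p = 3.6e-09, adjusted p = 0.181 with an estimated correlation). Of 21 MHC class I genes 18 rose and 2 fell, the same numbers adjusted over the list alone (camera adjusted p = 1.49e-07, adjusted p = 0.181 with an estimated correlation), with Nlrc5, the transactivator of class I genes, at 2.96 ± 0.16 (adjusted p = 1.4e-05). Of 16 monocyte and macrophage genes 14 rose, 14 adjusted over the list alone (camera adjusted p = 4.53e-07, adjusted p = 0.181 with an estimated correlation), and Adgre1, which encodes F4/80, rose by 1.44 ± 0.24. The classically activated macrophage list had 9 of 11 genes higher and 9 adjusted over the list alone (camera adjusted p = 5.19e-06, adjusted p = 0.181 with an estimated correlation). The alternatively activated list had 11 of 17 higher and 12 adjusted over the list alone (camera adjusted p = 8.52e-06, adjusted p = 0.181 with an estimated correlation). Tnf rose by 1.18 ± 0.16, and the arginase gene Arg1 gave 2.17 ± 1.27 (adjusted p = 0.18). Of 12 neutrophil genes 6 rose, 6 adjusted over the list alone (camera adjusted p = 0.0117, adjusted p = 0.528 with an estimated correlation).

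Epithelial and endothelial genes went the opposite way. Of 28 genes of prostate and seminal vesicle epithelium 13 fell and 15 did not pass, with 9 fallen when adjusted over the list alone (median −2.01, camera adjusted p = 0.000269, adjusted p = 0.523 with an estimated correlation). Krt14, a basal keratin, fell by 3.38 ± 0.68, and the androgen-dependent gene Pbsn was at least 1.46-fold lower (not above background in Tumor+Allo/Y). Of 19 endothelial genes 11 fell and 1 rose, the same numbers adjusted over the list alone (median −1.13, camera adjusted p = 0.00571, adjusted p = 0.432 with an estimated correlation). Of 26 fibroblast and smooth muscle genes 2 rose, 5 fell and 19 did not pass, with 2 risen and 1 fallen adjusted over the list alone (camera adjusted p = 0.481). The mean epithelium score was 12.06 ± 0.48 (SD, n = 3) in Allo/Y and 9.97 ± 0.76 in Tumor+Allo/Y. A score of 21 genes expressed in all leukocytes, a list drawn up after the data were seen, stood at 9.02 ± 0.11 in Allo/Y and 11.05 ± 0.25 in Tumor+Allo/Y, a difference of 2.02. Relative to that score, 30 of the 81 named genes called higher were still called higher and 14 were called lower, so Cxcl9 kept 2.96 and Ifng 0.85 while Cd3e stood at 0 and Tnf at −0.84. This scale lowers every gene by 2.02 alike, so a gene or list that rose by less turns lower by construction. On the same relative scale the interferon gamma list was higher by 0.99 ± 0.24 (adjusted p = 0.00301), the type I interferon list stood at 0 ± 0.17 (0.993), the T cell identity list at 0.33 ± 0.46 (0.569) and the cytotoxic effector list at −0.04 ± 0.31 (0.911). The MHC class I list was lower by that measure, at −0.75 ± 0.13 (0.000399). With the epithelium score as a covariate 2525 genes were called. All Allo/Y arrays had higher epithelium scores than every other array, so that fit extrapolates beyond the scores that the groups share.

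Tumor transfer alone against Allo/Y transfer alone compares the single treatments at 1 week. Gbp2b rose by 6.53 ± 0.65 (adjusted p = 0.000111), Cxcl9 by 4.7 ± 0.38 (adjusted p = 4.33e-05), Ifng by 2.87 ± 0.33 (adjusted p = 0.00024) and Cd8b1 by 3.8 ± 0.32 (adjusted p = 4.82e-05, with another probe at −0.41). Tgm4, the prostate transglutaminase, fell by 3.38 ± 0.82 (adjusted p = 0.01). Chil3 (4.53 ± 0.68), Chil4 (4.26 ± 0.72), Slfn1 (4.48 ± 0.4), Serpina3f (4.35 ± 0.49), Batf2 (4.3 ± 0.7), Calhm6 (4.21 ± 0.7) and the hexokinase gene Hk3 (4.09 ± 0.73) complete the largest rises together with Cfb, at least 17.9-fold higher and not above background in Allo/Y. The largest falls were those of Pate14 (−4.3 ± 1.06), Cyp4a12a (−3.98 ± 0.3, above background on 2 of 3 Tumor arrays) and Spink11 (−3.98 ± 0.6, on 1 of 3).

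In this comparison 2181 genes were higher and 2639 lower in Tumor (40.3%). All 14 T cell identity genes rose, 14 adjusted over the list alone (median 2.5, camera adjusted p = 2.35e-09, adjusted p = 0.192 with an estimated correlation), and 13 of 14 cytotoxic effector genes, 13 adjusted over the list alone (camera adjusted p = 1.15e-08, adjusted p = 0.153 with an estimated correlation). Prf1 gave −0.01 ± 0.27 on the probe used and 2.96, a call, on another. Of 9 inhibitory receptor genes 8 rose, 8 adjusted over the list alone (camera adjusted p = 1.73e-06, adjusted p = 0.153 with an estimated correlation), among them Ctla4 (3.85 ± 0.33) and Cd160 (2.22 ± 0.25). All 25 type I interferon genes and 21 of 22 interferon gamma genes rose, 25 and 21 adjusted over the list alone (both with camera adjusted p = 3.54e-13, adjusted p = 0.153 and 0.189 with an estimated correlation). Macrophage genes rose in 14 of 16 cases, 14 adjusted over the list alone (camera adjusted p = 1.46e-06, adjusted p = 0.192 with an estimated correlation). Of 12 neutrophil genes 3 rose and 9 did not pass, 3 adjusted over the list alone (camera adjusted p = 0.15). Of 34 proliferation genes 10 rose, 10 adjusted over the list alone (median 0.3, camera adjusted p = 0.0326, adjusted p = 0.701 with an estimated correlation), such as the centromere gene Cenpa (1.13 ± 0.26, adjusted p = 0.00765). Of 23 immediate early and heat shock genes 10 fell and 1 rose, the same numbers adjusted over the list alone (camera adjusted p = 0.0175, adjusted p = 0.543 with an estimated correlation), including the transcription factor gene Jun (−1.51 ± 0.39). With the epithelium score as a covariate that list was no longer called and its mean turned from −0.66 to 0.09, and within groups its score rose with the epithelium score (slope 0.33 ± 0.06, adjusted p = 0.00118).

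Epithelial genes fell in 12 of 28 cases and in 16 adjusted over the list alone (median −2.1, camera adjusted p = 1e-05, adjusted p = 0.401 with an estimated correlation). Endothelial genes fell in 13 of 19 cases, 13 adjusted over the list alone (camera adjusted p = 0.000424, adjusted p = 0.263 with an estimated correlation). The epithelium score of Tumor was 9.77 ± 1.44 (SD, n = 3), and the score of genes expressed in all leukocytes was 10.92 ± 0.31, higher by 1.89 than in Allo/Y. Relative to the latter, 32 of 83 named genes called higher were still called higher and 12 were called lower. Here too every gene is lowered alike, by 1.89, so smaller rises turn lower by construction. The interferon gamma list stood at 0.83 ± 0.24 relative to that score (adjusted p = 0.00941), the T cell identity list at 0.56 ± 0.46 (0.312), the neutrophil list at −1.04 ± 0.38 (0.0307) and the proliferation list at −1.55 ± 0.3 (0.000619). With the epithelium score as a covariate 1211 genes were called, again by extrapolation beyond the scores that the groups share. Without Allo/Y sample 1 the count was 3002. The changes against Allo/Y in Tumor+Allo/Y and in Tumor shared 1962 higher and 2476 lower genes, against 449 and 721 for independent lists. The same Allo/Y arrays serve both comparisons. In 200 simulations with unchanged groups sharing them at most 1 gene was shared in the higher direction and 0 in the lower. The simulated groups had no true change and independent genes, so hardly any gene could be called at all. They cannot show how much the shared arrays add to the overlap.

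**Figure D2:**
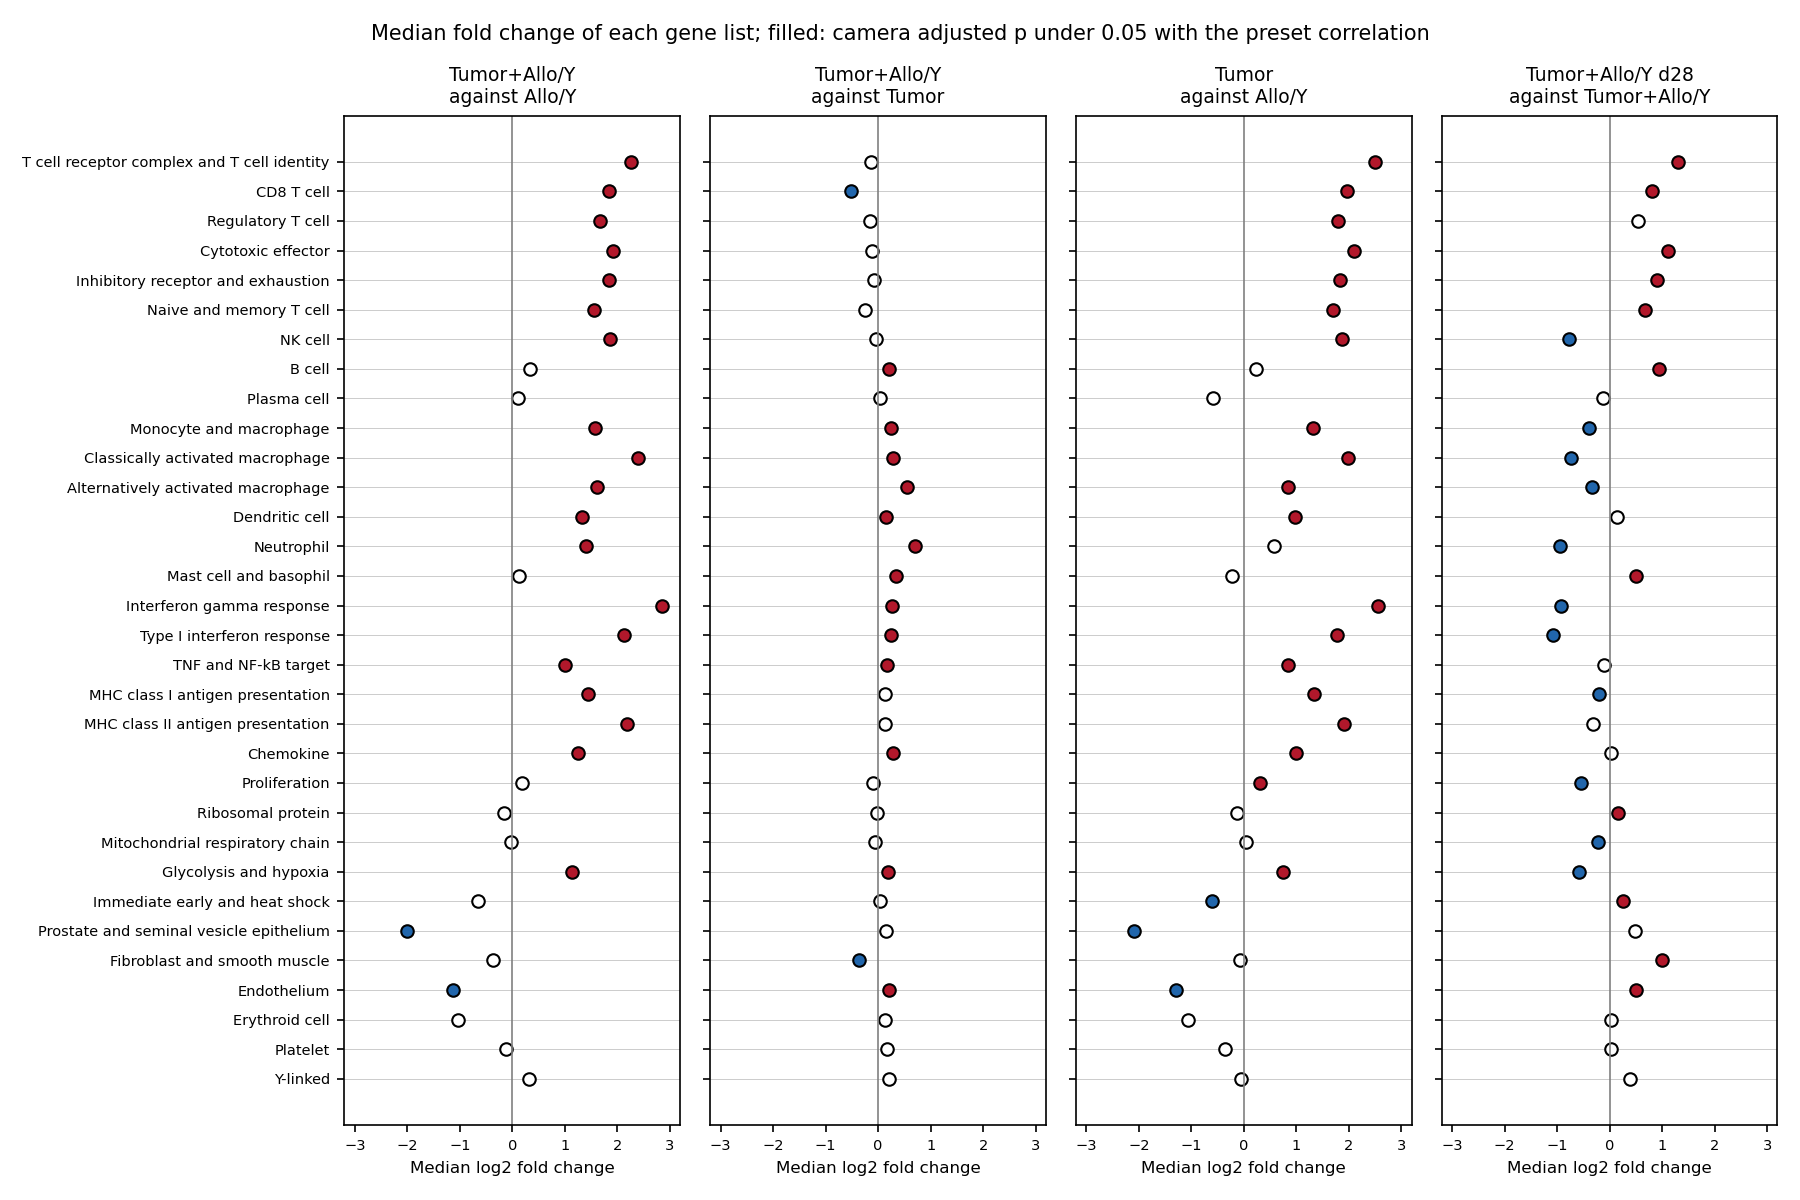
Median log2 fold change of the genes of 32 fixed lists in the 4 comparisons, with filled symbols where the camera adjusted p with the preset correlation was under 0.05 (red up, blue down). With an estimated correlation no list was called in any comparison. The lists of T cells, interferon responses and macrophages lie above 0 in both comparisons against Allo/Y and those of epithelium and endothelium below 0, while the medians for Tumor+Allo/Y against Tumor lie between −0.51 and 0.7.

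What Allo/Y transfer adds to Tumor transfer was asked by setting Tumor+Allo/Y against Tumor at 1 week. No gene was called by limma at an adjusted p under 0.05 (smallest 0.9997), while 451 of 11971 genes had an unadjusted p under 0.05. The groups did not overlap in 795 genes (6.6%, against 10% by chance). Ifng differed by 0.01 ± 0.33, Cxcl9 by 0.29 ± 0.38, Cd3e by −0.24 ± 0.4 and Foxp3 by 0.01 ± 0.22, with its other probes at −0.51 to −0.19 and none called. Larger values that did not pass include those of Chil3 (1.83 ± 0.68), the anti-inflammatory cytokine gene Il10 (1.08 ± 0.43), Tnf (0.52 ± 0.16), the endothelial adhesion gene Vcam1 (0.94 ± 0.39) and Cd8b1 (−0.83 ± 0.32), all with an adjusted p of 1. The neutrophil granule genes Ngp and Camp were at least 1.68-fold and 1.92-fold higher, not above background in Tumor, also with an adjusted p of 1. Since no gene was called against Tumor, none could be called higher or lower in Tumor+Allo/Y than in both single transfers.

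Camera with the preset correlation called 15 lists, 13 of them higher in Tumor+Allo/Y, although no member passed over all genes tested. The alternatively activated macrophage list had 17 measured genes, none risen or fallen and 0 adjusted over the list alone (median 0.55, camera adjusted p = 1.86e-06, adjusted p = 0.278 with an estimated correlation). The type I interferon list had 0 of 25 genes changed, 0 adjusted over the list alone (median 0.25, camera adjusted p = 7.04e-05, adjusted p = 0.581 with an estimated correlation). Of 12 neutrophil genes 0 rose over all genes and 2 adjusted over the list alone (median 0.7, camera adjusted p = 0.000304, adjusted p = 0.55 with an estimated correlation). The CD8 T cell list had 0 of 3 genes changed, 0 adjusted over the list alone (median −0.51, camera adjusted p = 0.0326, adjusted p = 0.55 with an estimated correlation). The fibroblast and smooth muscle list had 0 of 26, 0 adjusted over the list alone (median −0.36, camera adjusted p = 0.0151, adjusted p = 0.702 with an estimated correlation). Its mean turned from −0.27 to 0.09 and its call was lost without Tumor sample 4. Without Tumor+Allo/Y sample 9 only 6 lists were called, and no list was called by fry or with an estimated correlation. The arrays of both groups spread widely, with epithelium scores of 10.41, 10.78 and 8.13 in Tumor samples 4, 5 and 6 and of 9.71, 10.83 and 9.37 in Tumor+Allo/Y samples 7, 8 and 9. Neutrophil scores in the same order were 7.47, 8, 9.78, 9, 8.32 and 9.64. Probes above background numbered 20895, 20680, 18981, 19165, 21718 and 19774, fewest in samples 6, 7 and 9. Without samples 6 and 8, 2623 genes were called, a count that rests on arrays left out because of their values and on 2 arrays per group. Another split that set samples 4, 5 and 8 against 6, 7 and 9 called 4283 genes.

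How the infiltrate changed over time was asked by setting day 28 of the combined transfer against 1 week. Klrh1, a killer cell lectin-like receptor gene, rose by 4.04 ± 0.31 (adjusted p = 0.000906) and was above background on 1 of 3 arrays at 1 week. The related receptor gene Klrc1 rose by 2.3 ± 0.28 (adjusted p = 0.00863), Cd8b1 by 2.21 ± 0.32 (adjusted p = 0.0197) and Il7r, the interleukin-7 receptor of resting and memory T cells, by 2.26 ± 0.37 (adjusted p = 0.0243). Other probes of Cd8b1 gave 0.01 to 2.93, with 1 called. The interferon-induced gene Isg15 fell by 1.52 ± 0.22 (adjusted p = 0.0197), Irf7, the regulator of type I interferon, fell by 1.5 ± 0.27 (adjusted p = 0.0313) and the antiviral gene Rsad2 fell by 1.4 ± 0.27 (adjusted p = 0.0395). The secretoglobin gene Scgb2b27 fell by 4.47 ± 0.73 (adjusted p = 0.0243, above background on 2 of 3 arrays at day 28).

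Of 11971 genes 207 were higher and 42 lower at day 28 (2.1%). The other largest rises were those of the basal keratins Krt14 (3.41 ± 0.68) and Krt17 (2.74 ± 0.53), of Cartpt (3.1 ± 0.52) and Esm1 (2.4 ± 0.48), each above background on 2 of 3 arrays at 1 week, of B4galnt4 (2.14 ± 0.29, also 2 of 3), and of Pde4d (2.21 ± 0.34, with another probe at −0.15). Further falls were those of Scgb2b7 (−3.43 ± 0.7, on 1 of 3 arrays at day 28), Ifit2 (−1.65 ± 0.32), Klra7 (−1.57 ± 0.34), Oas1g (−1.47 ± 0.29), Cmpk2 (−1.43 ± 0.22) and Lpp (−1.4 ± 0.23). Other probes of Lpp gave −0.62 to −0.22, and none was called. The count of 249 depended on single arrays: it was 5, 14 and 394 without samples 10, 11 and 12, 44, 476 and 14 without samples 7, 8 and 9, 93 and 852 without samples 5 and 6, 62, 126 and 50 without samples 1, 2 and 3, and 7 when only these 2 groups were fitted. The named genes other than Klrh1 are read with that limit, as 36 of 37 lost their call without sample 10. Leaving out any of samples 1 to 6 acts on this count only through the pooled variance and its degrees of freedom. The median SD within a group was 0.133 in Allo/Y, 0.289 in Tumor, 0.254 in Tumor+Allo/Y and 0.193 at day 28.

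Of 14 T cell identity genes 4 rose and 10 did not pass, with 13 risen adjusted over the list alone (median 1.31, camera adjusted p = 7.06e-11, adjusted p = 0.32 with an estimated correlation). Cd3e rose by 2 ± 0.4 (adjusted p = 0.0396) and the costimulatory receptor gene Cd28 by 1.95 ± 0.41 (adjusted p = 0.0432). Of 14 cytotoxic effector genes 5 rose, 10 adjusted over the list alone (camera adjusted p = 9.71e-08, adjusted p = 0.302 with an estimated correlation), such as Gzmk (1.64 ± 0.26), while Ifng gave 1.07 ± 0.33 (adjusted p = 0.114). Of 9 inhibitory receptor genes 3 rose, 6 adjusted over the list alone (camera adjusted p = 4.4e-06, adjusted p = 0.302 with an estimated correlation), namely Lag3 (2.05 ± 0.25, adjusted p = 0.00863), Ctla4 (2.13 ± 0.33) and Tigit (1.62 ± 0.36). Of 7 naive and memory T cell genes 2 rose, 4 adjusted over the list alone (camera adjusted p = 3.25e-05, adjusted p = 0.302 with an estimated correlation). No B cell gene passed over all genes, but 9 of 12 rose adjusted over the list alone (median 0.95, camera adjusted p = 3.94e-06, adjusted p = 0.32 with an estimated correlation). Of 26 fibroblast and smooth muscle genes 4 rose, and 16 rose and 1 fell adjusted over the list alone (median 1, camera adjusted p = 3.14e-08, adjusted p = 0.379 with an estimated correlation). Among them were the matrix genes Lum (1.79 ± 0.33) and Bgn (1.52 ± 0.31), and Pdgfra (1.71 ± 0.29), for which another probe gave −0.08.

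Of 25 type I interferon genes 7 fell and 18 did not pass, with 22 fallen adjusted over the list alone (median −1.08, camera adjusted p = 1.72e-16, adjusted p = 0.302 with an estimated correlation). No interferon gamma response gene passed over all genes, and 11 of 22 fell adjusted over the list alone (median −0.92, camera adjusted p = 5.08e-09, adjusted p = 0.446 with an estimated correlation). Cxcl9 gave −0.73 ± 0.38 and Cxcl10 −1.37 ± 0.41 (adjusted p = 0.313 and 0.108). Of 10 NK cell genes 2 fell, 5 adjusted over the list alone (median −0.77, camera adjusted p = 0.00134, adjusted p = 0.446 with an estimated correlation), Klra7 and Klrb1c (−1.16 ± 0.26). Of 34 proliferation genes 0 passed over all genes and 7 fell adjusted over the list alone (median −0.54, camera adjusted p = 7.61e-08, adjusted p = 0.446 with an estimated correlation). Of 12 neutrophil genes 1 fell, 2 adjusted over the list alone (median −0.94, camera adjusted p = 0.0011, adjusted p = 0.446 with an estimated correlation), and Ngp was at least 1.75-fold lower, not above background at day 28. No macrophage gene passed among 16, 0 adjusted over the list alone (median −0.39, camera adjusted p = 0.00164, adjusted p = 0.446 with an estimated correlation). The epithelium list had 1 of 28 genes higher, 1 adjusted over the list alone (median 0.49, camera adjusted p = 0.0532). The score of genes expressed in all leukocytes differed by −0.04, and the T cell identity and type I interferon scores relative to it differed by 1.44 and −1.05.

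**Figure D3:**
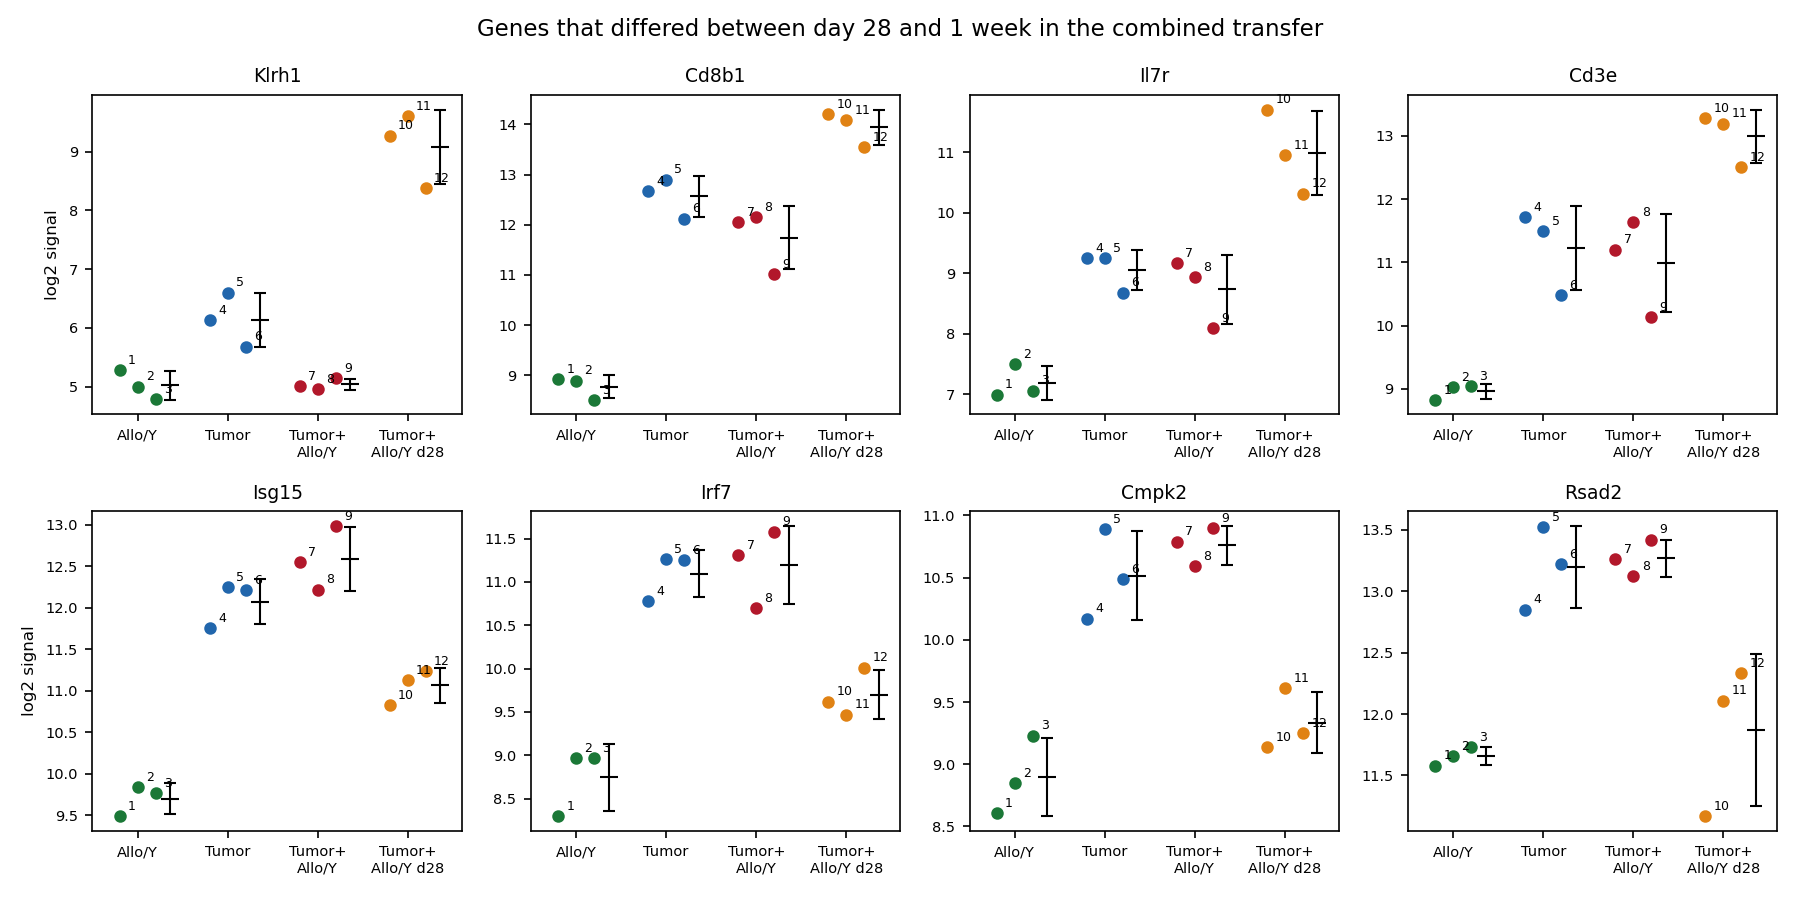
Log2 signal of Klrh1, Cd8b1, Il7r, Cd3e, Isg15, Irf7, Cmpk2 and Rsad2 per array in the 4 groups, with the group mean ± SD as a bar (n = 3). The first 4 genes lie higher and the last 4 lower at day 28 than at 1 week after the combined transfer.

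Several genes named in every comparison could not be read. Gzmb, Cd8a, Ncr1 and Xist were not detected, and Mki67 and Ddx3y have no named probe here. The CD4 T cell and eosinophil lists had 2 and 1 measured genes and were not tested.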

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

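The fits with the epithelium score as a covariate, with arrays shifted to an equal pan-leukocyte mean (over 21 genes expressed in all leukocytes) and without Tumor sample 6 and Tumor+Allo/Y sample 8 are tests chosen after the results were seen. Of 4483 gene values under the settings fixed earlier 4327 kept direction and side of the threshold, 80 became weaker, 75 stronger and 1 reversed, and of 1784 list values 1600, 144, 40 and 0. Leaving out single arrays kept 4620 of 4908 gene values and 1435 of 1536 list values, and the added settings kept 945 of 1227 and 327 of 384. Counted as kept are sign changes of values uncalled in both fits, 20, 33 and 36 for genes and 27, 42 and 28 for lists in the same order of settings. No normalization moved the median of all genes by more than 0.1. No paired analysis was possible because no replicate number is shared between groups. The BeadChip as a block was not run, as the files do not name it. Genes near background give bounds at most, and the fit with arrayWeights came with a convergence warning.

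Where a count moved, the cause was not tested unless named. Leaving out Allo/Y or Tumor samples can move the count over time only through the pooled variance and its degrees of freedom. For day 28 against 1 week, 75th percentile scaling called 147 genes, only the 2 groups in the fit 7, arrayWeights 2872, the epithelium covariate 611, the pan-leukocyte shift 27 and the fit without samples 6 and 8 3105. Genes differing among the 4 groups numbered 8505 with arrayWeights and 11409 with the pan-leukocyte shift. Against Allo/Y, the covariate gave 2525 genes for Tumor+Allo/Y and 1211 for Tumor, and the shift gave 11196 and 11169. Without samples 6 and 8, Tumor+Allo/Y against Tumor gave 2623 genes, with 892 higher and 1568 lower than in both single transfers. Of the lists, 0 were called with an estimated correlation in each of the 4 comparisons. For Tumor+Allo/Y against Tumor 9 lists were called with no filter and 0 by fry, and fry called 8 over time.

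Leaving out single arrays gave 3948 to 6600 genes for Tumor+Allo/Y against Allo/Y, 0 to 1 against Tumor, 3002 to 5334 for Tumor against Allo/Y, 5 to 852 over time and 3357 to 6618 among the 4 groups. Genes higher than in both single transfers numbered 0 to 1 and genes lower 0 to 0, which cannot exceed the calls against Tumor. The lists numbered 21 to 23, 6 to 15, 21 to 22 and 18 to 23 in the same order of comparisons. The single gene was Galnt9, at 1.23 without Tumor sample 6 and chosen after its value was seen. The 3002 genes came without Allo/Y sample 1, the 6 lists without Tumor+Allo/Y sample 9, and among the 4 groups 3357, 3650 and 3534 genes without Allo/Y samples 1, 2 and 3. Over time the count was 62, 126 and 50 without Allo/Y samples 1, 2 and 3, 93 and 852 without Tumor samples 5 and 6, 44, 476 and 14 without Tumor+Allo/Y samples 7, 8 and 9, and 5, 14 and 394 without day 28 samples 10, 11 and 12. The 5 genes left without sample 10 were Klrh1 (3.95), C7 (2.17), Themis (1.77), P2ry10 (1.74) and Wnt10b (1.32), the last 4 chosen after their values were seen. Of 37 named genes called over time, 36, 33 and 4 lost their call without samples 10, 11 and 12, 25, 4 and 31 without samples 7, 8 and 9, 5, 18 and 0 without samples 4, 5 and 6, and 19, 16 and 23 without samples 1, 2 and 3. Against Allo/Y, at most 1 of 99 named calls for Tumor+Allo/Y and at most 8 of 105 for Tumor were lost when a single array was left out. With the epithelium covariate 12 named calls were lost for Tumor+Allo/Y, and 31 for Tumor besides Mme, which turned sign. The pan-leukocyte shift weakened 21 and 26, apart from those that turned sign. Klrh1 kept its call under all 26 settings that gave it a value, at 2.89 to 4.4 (adjusted p = 6.83e-05 to 0.0185).

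Reversed values follow, with the cause not tested unless named. Prf1 in Tumor against Allo/Y was 1.48 as the mean of its probes, which bring in the probe that rose. In Tumor+Allo/Y against Tumor the fibroblast list was 0.09 without Tumor sample 4, the epithelium list −0.63 without Tumor sample 6 and the T cell identity list 0.25 without Tumor+Allo/Y sample 9. With single arrays left out, these lists ranged from −0.74 to 0.09, from −0.63 to 0.7 and from −0.42 to 0.25. Without samples 6 and 8 that comparison gave −1.06 for the epithelium list, −0.61 for the erythroid list, 1.4 for Nos2 and −1.56 for Krt8. With the covariate the epithelium list was 0 in both comparisons against Allo/Y, by construction, the fibroblast list 0.81 in Tumor+Allo/Y, and in Tumor the mitochondrial list −0.18, the immediate early list 0.09 and Mme 0.07. The pan-leukocyte shift lowers all genes of the groups set against Allo/Y by construction, so 36 named genes of Tumor+Allo/Y and 30 of Tumor turned sign, 14 and 12 of them called both ways. In Tumor+Allo/Y these stood at −0.18 for Eomes, −1.08 for Crtam, −0.35 for Il2ra, −0.12 for Cst7, −0.11 for Cd244a, −0.1 for Havcr2, −0.17 for Btla, −0.29 for Ccr7, −1.24 for Bcl2, −0.69 for C1qb, −0.67 for C1qa, −0.38 for Lyz2, −0.78 for C1qc, −0.84 for Tnf, −0.2 for Clec10a, −0.03 for Batf3, −0.43 for Bst2, −0.87 for Ngp, −0.22 for Icam1, −0.33 for Nfkb2, −0.21 for H2-T10, −0.3 for Tapbpl, −1.05 for H2-Ab1, −0.05 for Ccl12, −0.66 for P4ha1, −0.89 for Gapdh, −1.1 for Ldha, −1.94 for Prf1, 0 for Cd3e, −0.93 for Cd4, −1.52 for Foxp3, −1.36 for Pdcd1, −1.66 for Ms4a1, −0.59 for Adgre1, −1.4 for Mrc1 and −1.66 for Eif2s3y. In Tumor they stood at −0.45 for Crtam, −0.11 for Il2ra, −0.05 for Havcr2, −0.19 for Ccr7, −0.01 for Il7r, −0.63 for C1qc, −0.7 for C1qb, −0.75 for C1qa, −0.19 for Batf3, −0.31 for Icam1, −0.92 for Relb, −0.08 for H2-T10, −0.96 for H2-Ab1, −0.28 for Ccl12, −0.38 for Ccl7, −0.77 for Cenpa, −1.02 for Plk1, −0.7 for Birc5, −0.93 for Cdca8, −0.82 for Gapdh, −1.06 for Ldha, −0.1 for Egln3, −1.23 for Tnf, −1.1 for Cd4, −1.4 for Foxp3, −1.43 for Pdcd1, −1.81 for Ms4a1, −0.57 for Adgre1, −1.49 for Mrc1 and −1.74 for Eif2s3y. Camera's direction, which compares the t statistics of a list with those of all other genes, also turned under the shift. In Tumor+Allo/Y it turned for the mitochondrial (−1.95), epithelium (−4.11) and fibroblast (−2.25) lists. In Tumor it turned for the mitochondrial (−1.81) and epithelium (−4.18) lists. The values in brackets are the list means under the shift. Because the shift lowers all genes of an array alike, no list changed its log2 difference relative to the other genes. The turned directions concern t statistics only and do not show that a list rose relative to other genes.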

Other observations

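All tests of list scores relative to other scores, the comparison of 6 normalizations, the slope on the epithelium score and the counts of other splits for the genes of Tumor+Allo/Y against Tumor and of day 28 were chosen only after the results were seen, as was the bound of 1 log2 unit for intervals. The exchange of labels and the remaining splits were set out as tests beforehand.

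Genes of glycolysis, hypoxia and inflammation also differed between Tumor+Allo/Y and Allo/Y, while the mitochondrial respiratory chain list was not called (mean 0.07, camera adjusted p = 0.802). Of 25 glycolysis and hypoxia genes 18 rose and 2 fell, 20 and 2 adjusted over the list alone (median 1.14, camera adjusted p = 8.48e-05, adjusted p = 0.51 with an estimated correlation). Pfkp, a phosphofructokinase gene, rose by 3.57 ± 0.4 and the lactate dehydrogenase gene Ldha by 0.92 ± 0.18 (n = 3 per group, all 3 arrays higher). Of 27 TNF and NF-kB targets 17 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 1.4e-06, adjusted p = 0.118 with an estimated correlation), among them Traf1 (2.09 ± 0.19). Of 27 chemokine genes 14 rose and 2 fell, 16 and 2 adjusted over the list alone (camera adjusted p = 4.5e-05, adjusted p = 0.118 with an estimated correlation), such as Ccl12 (1.97 ± 0.17). Of 14 dendritic cell genes 8 rose, 8 adjusted over the list alone (camera adjusted p = 0.00018, adjusted p = 0.151 with an estimated correlation), including Clec9a and Batf3 of cross-presenting dendritic cells (2.2 ± 0.29 and 1.99 ± 0.24). Relative to the pan-leukocyte score these lists, the respiratory chain aside, were lower in Tumor+Allo/Y, at −0.99 ± 0.18 for glycolysis and hypoxia (adjusted p = 0.000582), −0.89 ± 0.14 for TNF and NF-kB targets (0.000199), −0.84 ± 0.19 for chemokines (0.00206) and −0.9 ± 0.24 for dendritic cells (0.00481). That scale lowers genes also expressed outside leukocytes by construction, as for the ribosomal protein (−2.21) and respiratory chain (−1.95) lists. The values therefore do not show lower activity per leukocyte. Of 8 plasma cell genes 1 rose and 3 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.676), with a median of 0.11 and a mean of −0.24.

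Over time, 0 of 25 glycolysis and hypoxia genes passed, 0 adjusted over the list alone (median −0.58, camera adjusted p = 8.42e-06, adjusted p = 0.446 with an estimated correlation). The respiratory chain list had 0 of 38 genes changed, 0 adjusted over the list alone (median −0.22, camera adjusted p = 0.000255, adjusted p = 0.446 with an estimated correlation). The ribosomal protein list had 0 of 32, 0 adjusted over the list alone (median 0.16, camera adjusted p = 0.0011, adjusted p = 0.446 with an estimated correlation), and its mean of 0.17 became −0.04 with 75th percentile scaling.

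The T cell identity, macrophage and interferon gamma lists were lower and the epithelium list higher in Allo/Y than in Tumor+Allo/Y, calls lost with an estimated correlation (adjusted p = 0.213, 0.181, 0.181 and 0.523). A lower share of leukocyte RNA in the Allo/Y samples, as the whole cause, is argued against for interferon gamma genes, whose score relative to the pan-leukocyte score was higher by 0.99 ± 0.24 in Tumor+Allo/Y (adjusted p = 0.00301). The choice of between-array normalization is argued against by a pan-leukocyte difference of at least 1.82 under 6 normalizations. All 6 scale the arrays to each other, so a bias common to such scaling was not tested. A drop common to all leukocytes is also argued against by the mast cell list alone. Its score before any subtraction differed by only 0.05 ± 0.26, against 2.02 for the pan-leukocyte score. Its relative score of −1.97 ± 0.38 (adjusted p = 0.000675) restates that. Relative scores of −0.9 ± 0.24 for dendritic cells (0.00481), −2.26 ± 0.27 for plasma cells (2.78e-05) and −1.49 ± 0.23 for B cells (0.000206) decide less. The dendritic cell list did rise, from a low score in Allo/Y (7.23). No immunoglobulin gene of the plasma cell list was measured, and the B cell genes lay near background. Any list unchanged between the groups is lowered by the pan-leukocyte difference of 2.02 on this scale, as the ribosomal protein list was (−2.21 ± 0.22). For macrophage genes alone a lower share could still account for the difference (relative score −0.2, 95% interval −0.62 to 0.22), and for T cell genes 0.33 (−0.73 to 1.39) is too imprecise to decide. The pan-leukocyte score is not neutral between cell types. Within groups its slope on the epithelium score (−0.23 ± 0.05) had the sign of the macrophage slope (−0.39 ± 0.07), and the T cell identity slope was 0.34 ± 0.12. A macrophage score that moves with the pan-leukocyte score therefore decides little. Epithelial cells carried through the CD45 selection and free epithelial RNA cannot be told apart, since no measure of the purity of the selection was available. A difference between the transfers in the infiltrate itself stays open and untested.

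Tumor sample 6 lay near Tumor+Allo/Y samples 7 and 9, and the sample labelled Tumor+Allo/Y 8 near Tumor samples 4 and 5, and samples 6, 7 and 9 had the fewest probes above background (18981, 19165 and 19774, against 20895, 20680 and 21718 in samples 4, 5 and 8). A differing share of epithelial RNA, as the whole cause, would move T cell and macrophage scores alike, but within groups the slope of their difference on the epithelium score was 0.73 ± 0.15 (95% interval 0.37 to 1.1, adjusted p = 0.000754). That test replaced the slope of the T cell score alone (0.34 ± 0.12, adjusted p = 0.0564), which would not have decided. Samples 6 and 8 themselves enter the slope of the difference, and it was not fitted without them. It therefore partly restates their position and cannot decide against epithelial RNA by itself. An exchange of the 2 labels may account for the pattern but is not shown by it: on 50 genes chosen from samples 4, 5, 7 and 9 after removal of the epithelium trend sample 6 was nearer the Tumor+Allo/Y mean on 48 and sample 8 nearer the Tumor mean on 47, counts that largely restate the resemblance. Those genes also carry any difference between mice in myeloid content or in RNA or array quality, both of which stay open and untested, and neither sample lay at the other label's mean (sample 6 at 1.56 and sample 8 at 0.32 on a scale from 0 at Tumor to 1 at Tumor+Allo/Y), so no label was changed.

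At day 28 the T cell identity list was higher and the type I and gamma interferon lists lower than at 1 week, calls lost with an estimated correlation (adjusted p = 0.32, 0.302 and 0.446). A changed share of leukocytes, as the whole cause, is argued against by the scores relative to the pan-leukocyte score, 1.44 ± 0.46 for T cell identity (adjusted p = 0.0333) and −1.05 ± 0.17 for type I interferon (adjusted p = 0.00255). Whether fewer myeloid cells account for the lower interferon signal was not decided. The type I interferon score relative to the macrophage score differed by −0.44 (95% interval −0.96 to 0.09, adjusted p = 0.145). That interval holds 0 but also reaches nearly the whole fall of the type I interferon score (−1.09 ± 0.23). The macrophage score itself differed by −0.65 ± 0.29 (limma adjusted p = 0.101). A change of the infiltrate between 1 week and day 28, which the design names, stays open and untested.

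Among 100 splits of the 12 arrays into 4 groups of 3, only the real one, 1 of 100, called as many genes as 5479, with 4752 the highest other. That share makes chance unlikely for a difference somewhere among the 4 groups, but 100 splits cannot give a smaller one. It does not show that every pair of groups differs. For each pair of groups the 10 splits are too few for a share under 0.05. For genes, the real split and the highest other gave 5736 and 0 for Tumor+Allo/Y against Allo/Y, 4820 and 1 for Tumor against Allo/Y, and 249 and 0 over time, with 1 of 10 splits as large in each. For Tumor+Allo/Y against Tumor they gave 0 and 4283, all 10 splits being as large, and the 4283 genes, from samples 4, 5 and 8 against 6, 7 and 9, point to a structure of the samples that the labels do not follow. For lists called by camera with the preset correlation, the real split and the highest other gave 21 and 22, 15 and 20, 22 and 24, and 22 and 18 for Tumor+Allo/Y against Allo/Y, Tumor+Allo/Y against Tumor, Tumor against Allo/Y and over time, with 3, 4, 2 and 1 of 10 splits as large.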
